A study of Rattus norvegicus with 9 samples.

How the data were processed

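Poly-A RNA from the middle of a femoral fracture in rats was sequenced in 9 libraries, 3 for each of 3 groups. The groups received a gel alone (Gel), the gel with the bisphosphonate that the labels call ALN (ALN gel), or the gel with a magnesium and ALN material (Mg-ALN gel). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, messenger RNA was bound with poly-T beads, cDNA was primed with random hexamers, and fragments were selected by size before amplification. The protocols do not mention marking of the strand, so the values of genes that overlap another gene on either strand are uncertain, as are those of near-identical paralogs and pseudogenes.

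The main values were the read counts per gene that the authors deposited as whole numbers, with no normalization. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5, without saying what each was used for. The genome build was not given in the sources used here, so coordinates are those of the deposited table. The authors also deposited FPKM values. Checked against the counts, each FPKM value was the count divided by the gene length and by 1 constant per library. That constant corresponded to 0.804 to 1.19 times the column total, so the FPKM values already hold a scaling between libraries. The count table held 35360 genes, of which 2477 loci had no biotype. It held no line of total or unassigned reads.

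Total counts per library lay between 13388689 and 18763270. Before any test, pairs of libraries were compared by a chi-square test of their counts. The lowest chi-square per degree of freedom was 72.3, far above sampling noise, so all 9 libraries were kept as separate replicates. The labels do not say that the replicates are separate animals, and the p-values therefore measure only the spread between these samples, which may be technical in part. The groups share replicate numbers. Between Gel and ALN gel, deviations from the group means correlated across genes with r = 0.341, 0.419 and 0.226 for libraries of the same number. For other numbers r was −0.283 to −0.0125. Deviations cancel within a group, so positive values for some pairs force negative ones for others. With 3 libraries per group such a match can arise by chance, so it does not establish a pairing. The same-number values were −0.0767, −0.0452 and −0.199 between Gel and Mg-ALN gel and 0.130, −0.120 and −0.127 between ALN gel and Mg-ALN gel. There the highest value was 0.320, for ALN gel library 3 with Mg-ALN gel library 2, so the numbers showed no pairing. The main fit stayed without the block, and the fit with it, over all 9 libraries, was an alternative.

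Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered by filterByExpr with its default settings, which left 15460 genes, and libraries were scaled by TMM. All 9 libraries entered 1 edgeR quasi-likelihood fit with a coefficient per group (robust option off). The comparisons were ALN gel against Gel, Mg-ALN gel against ALN gel, Mg-ALN gel against Gel, and a joint test of differences among the 3 groups. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. CPM values used the TMM-scaled library sizes, and log2 CPM values had a prior count of 0.5. Group values are means with the SD over 3 libraries.

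A total of 34 gene lists for pathways and cell types was tested with limma's camera on voom values, with a correlation between genes preset at 0.01. P-values were adjusted over all 102 tests, 34 lists in 3 comparisons. This adjustment can give many lists the same adjusted p although their unadjusted p-values differ. The lists held 531 entries, of which 520 matched a gene of the table by symbol, by mitochondrial gene name or through a RefSeq gene table of assembly GRCr8 that was used for names only. Of the others, 11 did not match, and 6 entries repeated a gene already in their list. Members of a list were also adjusted over the list alone, with the edgeR p-values of its members only. The list score of a library is the mean over members of the log2 CPM centred on each gene. Scores and single genes were compared by exact permutation tests. With 3 libraries against 3 such a test cannot give a p under 0.1, and over the 280 ways to form 3 groups of 3 its smallest p is 0.00357.

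The groups, tests, lists, alternatives and rule for named genes were chosen before the data were examined. The rule named 13 fixed genes in every comparison (Sost, Tgfb1, Ccn2, Col1a1, Col3a1, Acta2, Postn, Bglap, Dmp1, Acp5, Ctsk, Fdps and Trpm7), up to 8 higher and 8 lower protein-coding genes with adjusted p under the threshold, a mean of at least 2 CPM in the higher group and no overlap between the groups, up to 4 passing members of each list, and list genes that describe libraries. No gene passed in edgeR, so the parts of the rule that need a passing gene named none. The exceptions were chosen after the values were seen: the 4 higher and 4 lower genes with the smallest p in each comparison, list members that passed when adjusted over the list alone, and a few further genes said to be so chosen where they appear. The result of 1 gene so chosen is not reported here.

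The pipeline was tested on simulated data drawn from the means and sizes of the real libraries for ALN gel against Gel, over 15460 genes with 200 of them changed. A 2-fold change was recovered for 0% of the changed genes, a 4-fold change for 44% with 6 false calls, and a 16-fold change for 90.5% with 5 false calls. In the list test, 0 of 102 tests called a list with nothing changed, and a fibrosis list shifted by 1 on the log2 scale gave an adjusted p of 3.6e-09. The simulated genes were drawn independently, so the list test was not tried on correlated genes, and splits of the real libraries other than by group called 6 to 21 of the 34 lists.

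Alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom with sample quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 or with a log2 fold change of at least 1, and camera with an estimated correlation or fry in place of camera with the preset one. DESeq2 gave no adjusted p for 1589, 394 and 94 genes in the 3 comparisons in the order above, and these stayed missing. Alternatives added after the data were seen left out the mitochondrially encoded genes, used the mitochondrial share or the score of the osteoclast or mature skeletal muscle list as a covariate, left out ALN gel library 1 together with Mg-ALN gel library 1, and compared further targets of the sterol regulators SREBP2 and LXR between Gel and the other 6 libraries by the 84 ways to choose 3 of 9. The 34 lists were put to the same test, but Gel was set apart only after the scores had been seen, so those p-values are not used. Comparisons that share a group were set against 20 simulated data sets with no effect. Reads, sequence variants and splicing were not analysed here.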

Results

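RNA from the middle of rat femoral fractures was profiled in 9 libraries, 3 each from fractures given Gel, ALN gel or Mg-ALN gel. The Gel libraries held 13998652, 16053487 and 13388689 counts, the ALN gel libraries 16837698, 15880939 and 14479060, and the Mg-ALN gel libraries 13750327, 15125041 and 18763270. The spread between libraries of a group was wide, with a common biological coefficient of variation of 51.4%. Over the tested genes, log2 CPM of libraries of the same group correlated with a mean r of 0.872 and those of different groups with a mean r of 0.863, which are correlations across genes. Mitochondrially encoded genes took 17.5%, 5.40% and 4.16% of the counts in the Gel libraries 1 to 3, 39.5%, 15.6% and 7.61% in the ALN gel libraries, and 11.2%, 10.6% and 31.6% in the Mg-ALN gel libraries. The share of Col1a1, which encodes the main chain of type I collagen, was 9.78%, 4.26% and 5.63% in Gel, 0.823%, 2.12% and 3.32% in ALN gel, and 2.45%, 3.42% and 2.80% in Mg-ALN gel. Markers of tissue composition varied within groups. Acta1, the actin of skeletal muscle, had 219, 440 and 52851 counts in the Gel libraries, 4954, 448 and 10984 in ALN gel, and 821, 623 and 14 in Mg-ALN gel.

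The study's design names Sost, TGF-β signalling and fibrosis as its subject. Sost (ENSRNOG00000020805, chromosome 10, 89897087 to 89900131), which encodes the osteocyte Wnt antagonist sclerostin, had 26, 5 and 5 counts in the Gel libraries, 119, 71 and 114 in ALN gel, and 3, 2 and 12 in Mg-ALN gel. This corresponded to 0.815 ± 0.897, 6.87 ± 2.39 and 0.373 ± 0.342 CPM (mean ± SD, n = 3 each). Each ALN gel library lay above each of the other 6. The log2 fold change was 3.08 (SE 0.92) in ALN gel against Gel, −4.17 (SE 0.98) in Mg-ALN gel against ALN gel, and −1.09 (SE 0.92) in Mg-ALN gel against Gel. Over all genes tested, Sost passed in none of the 3 comparisons by edgeR, with adjusted p-values of 0.528, 0.496 and 0.697 in this order. When adjusted over the list alone, it passed in Mg-ALN gel against ALN gel in the osteocyte list and in the list of Wnt antagonists. DESeq2 called it in that comparison with an adjusted p of 0.00195, and limma-voom with quality weights called it in ALN gel against Gel with an adjusted p of 0.0397 and a log2 fold change of 3.83. The exact permutation p over the 3 groups was 0.0179, unadjusted for the number of genes. The difference between Mg-ALN gel and Gel rested on Gel library 1, without which its log2 fold change was 0.32.

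**Figure D1:**
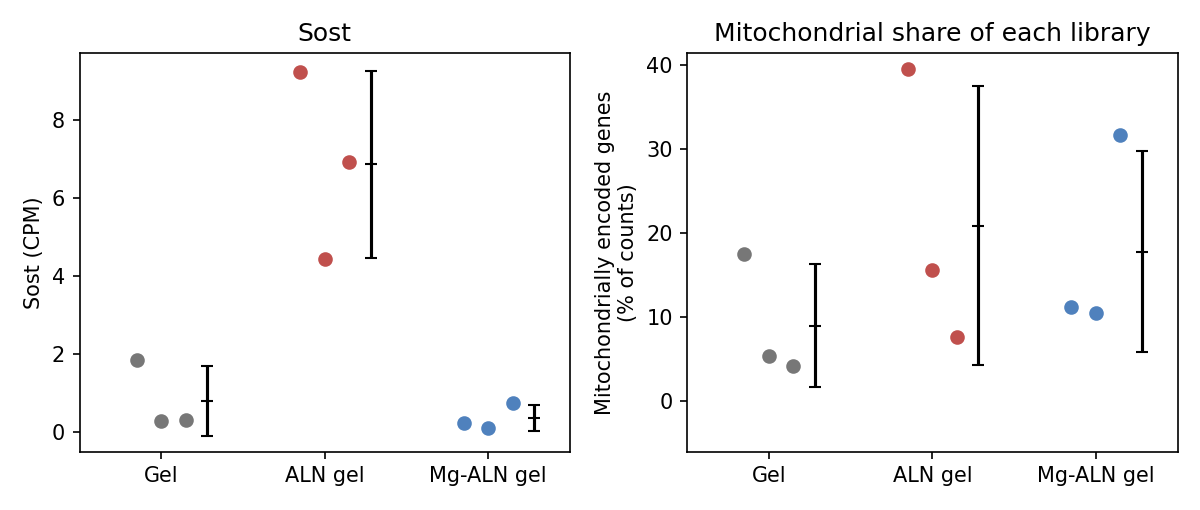
CPM of Sost (left) and the percentage of counts from mitochondrially encoded genes (right) in each library (points), with the mean and SD of each group (bars, n = 3). The ALN gel libraries had a mean of 6.87 CPM of Sost and a mean mitochondrial share of 20.9%, against 0.815 CPM and 9.01% in Gel and 0.373 CPM and 17.8% in Mg-ALN gel.

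The first comparison, ALN gel against Gel, asks how the bisphosphonate changed the tissue. Genes of mevalonate and sterol synthesis, the pathway that holds the target of nitrogen-containing bisphosphonates, were higher in ALN gel, with positive log2 fold changes for 20 of 21 members and a median of 0.72 (camera adjusted p = 2.35e-11, and adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone, 10 of 21 members rose, against 0 over all genes tested. Fdps (ENSRNOG00000043377, chromosome 2, 188392858 to 188413219), the farnesyl diphosphate synthase that these drugs inhibit, went from 43.9 ± 0.813 to 81 ± 6.56 CPM (n = 3, log2 fold change 0.88, SE 0.20). Insig1, a sterol-regulated brake on the pathway, went from 96.8 ± 17.1 to 449 ± 127 CPM (2.21, SE 0.33), and Idi1, the isomerase just before Fdps, from 11.8 ± 1.06 to 30.2 ± 5.07 CPM (1.35, SE 0.22). Msmo1 and Cyp51, enzymes of late sterol synthesis, had log2 fold changes of 1.25 and 0.98. The count of 10 was 5 without Gel library 2 and 6 without ALN gel library 2, and the median was 0.37 without ALN gel library 2.

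Osteoclast genes were also higher in ALN gel, all 15 of 15 with a median log2 fold change of 1.48 (camera adjusted p = 7.61e-11, and adjusted p = 0.78 with an estimated correlation). Of the 15, 3 rose when adjusted over the list alone, against 0 over all genes tested. These were Tnfrsf11a, the receptor for the osteoclast differentiation factor RANKL (30.3 ± 18.1 to 84.5 ± 12.3 CPM, n = 3), Calcr, the calcitonin receptor (3.63 ± 2.96 to 20.5 ± 3.2 CPM), and Tcirg1, a subunit of the osteoclast proton pump (281 ± 107 to 584 ± 83.1 CPM). Ctsk, the protease that degrades bone collagen, and Acp5, the tartrate-resistant acid phosphatase, did not pass, with log2 fold changes of 1.61 (SE 0.76) and 1.43 (SE 0.89). The count of 3 was 11 without Gel library 1, 7 without Mg-ALN gel library 1, and 0 without Gel library 2 or 3, without any 1 of the ALN gel libraries, or without Mg-ALN gel library 2, each left out on its own. It was also 0 with RLE scaling, with the replicate number as a block and with the mitochondrial share as a covariate. With the muscle score as a covariate it was 9. The median was 2.39 without Gel library 1.

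Nuclear-encoded genes of oxidative phosphorylation were higher in ALN gel for 19 of 19 members, with a median of 0.88 (camera adjusted p = 1.06e-15, and adjusted p = 0.78 with an estimated correlation). Of the 19, 15 rose when adjusted over the list alone, against 0 over all genes tested, among them Cycs, the electron carrier cytochrome c (93.5 ± 14.0 to 193 ± 46.7 CPM, n = 3), Sdhb of complex II (83.5 ± 8.87 to 154 ± 34.6 CPM) and Atp5f1b of the ATP synthase (658 ± 139 to 1266 ± 233 CPM). Mitochondrially encoded transcripts moved the same way, with a median of 1.55 over 13 members (adjusted p = 1.82e-04, and 0.78 with an estimated correlation), and the mean mitochondrial share of the libraries was 9.01 ± 7.35% in Gel and 20.9 ± 16.6% in ALN gel. The count of 15 was 0 without Gel library 2, Gel library 3, ALN gel library 1 or ALN gel library 2, each left out on its own, and 0 with the mitochondrial share as a covariate. The mitochondrially encoded list lost its call without ALN gel library 1 (median 0.37, adjusted p = 0.0694) and had a median of 2.63 without Gel library 1.

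The fibrosis matrix list, made up of collagens and other matrix proteins, had 23 of 25 members with negative values and a median of −0.55 (camera adjusted p = 2.04e-07, and adjusted p = 0.78 with an estimated correlation). None of its members (0) passed when adjusted over the list alone. Col1a1 (chromosome 10, 82745801 to 82762789) had 61107 ± 31773 CPM in Gel and 20358 ± 9235 in ALN gel (n = 3, log2 fold change −1.59, SE 0.65, edgeR adjusted p = 0.583), with no overlap between the groups. Col3a1, of type III collagen, had −0.52 (SE 0.88), and Postn, the matrix protein periostin, −0.86 (SE 0.59). The list scores of the ALN gel libraries were −2.26, −0.51 and 0.65, and those of Gel −0.06, 0.41 and 0.67, so the groups overlapped. Within each replicate number the score was lower, and the mitochondrial share higher, in ALN gel than in Gel. For number 3 the scores were nearly equal (0.65 against 0.67), and a pairing by number is not established. The median was −0.30 without ALN gel library 1, −1.43 without ALN gel library 3 and −0.88 with the replicate number as a block. ALN gel library 1, with the lowest score, also had the highest mitochondrial share. With the mitochondrial share as a covariate the median was −0.13 and the call ended (adjusted p = 0.0648), as it did with the osteoclast score as a covariate (adjusted p = 0.204). Immediate early genes, the first genes induced by stimuli and listed beforehand as a marker of RNA quality, had negative values in 13 of 13 members with a median of −0.92 (adjusted p = 1.29e-05, and 0.78 with an estimated correlation). With the mitochondrial share as a covariate this call ended too (adjusted p = 0.118), and the median was −0.55 without ALN gel library 1 and −0.61 without Gel library 3.

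For TGF-β, the ligands, receptors and activators had a median of −0.38 with 13 of 18 members negative (camera adjusted p = 0.00761, and adjusted p = 0.78 with an estimated correlation), a call that was lost without ALN gel library 1 (−0.09, adjusted p = 0.164), with −0.66 without ALN gel library 3. Response genes of TGF-β had a median of −0.26 and were not called (adjusted p = 0.0796), but were called without Gel library 2 (0.0474), without ALN gel library 3 (0.0103) and with the replicate number as a block (median −0.40, 0.0468). Those calls are at the preset correlation, and the list had an adjusted p = 0.78 with an estimated correlation over all libraries. Its median was −0.15 without ALN gel library 1 and −0.77 without ALN gel library 3. Adjusted over the list alone, 0 members of either list passed. Tgfb1, the ligand itself, had 231 ± 25.0 CPM in Gel and 164 ± 43.2 in ALN gel (n = 3, −0.49, SE 0.24), Ccn2, a TGF-β target, 0.05 (SE 0.79), and Acta2, the actin of myofibroblasts, −1.24 (SE 0.87), none of which passed. The direction for Ccn2 turned with no low-count filter (−0.04). Further lists were called but lost the call when at least 1 library was left out. These were the myofibroblast list (median −0.56, adjusted p = 0.0032), inflammatory cytokines (−2.27, 0.00414), matrix proteases (−0.77, 0.0169), smooth muscle and pericyte genes (−0.43, 0.0204), BMP signalling (−0.37, 0.0272), Wnt targets (−0.90, 0.0334) and, in the higher direction, erythroid genes (1.08, 0.00991). Their adjusted p-values with an estimated correlation were 0.78 to 0.804. Without ALN gel library 1 the calls ended for myofibroblast genes (adjusted p = 0.0602), matrix proteases (median −0.36, 0.291), smooth muscle and pericyte genes (−0.11, 0.484), BMP signalling (−0.23, 0.111), Wnt targets (0.103) and erythroid genes (0.09, 0.0886). Without Gel library 1 they ended for Wnt targets (−0.23, 0.351), BMP signalling (0.355) and smooth muscle genes (0.0756), and the medians were −1.22 for matrix proteases and 4.28 for erythroid genes. Without Gel library 2 the inflammatory (0.213), protease (0.304) and erythroid (0.53, 0.141) calls ended, and without Gel library 3 the inflammatory (0.0766), protease (0.141) and smooth muscle (0.0564) calls, with 0.55 for erythroid genes. The Wnt target (0.0905) and smooth muscle (0.0541) calls ended without ALN gel library 2, with −4.88 for inflammatory genes. The inflammatory call ended without ALN gel library 3 (0.130), where the medians were −0.87 for myofibroblast genes, −1.32 for proteases and −1.26 for smooth muscle genes. The bone cell genes Bglap (osteocalcin) and Dmp1 had log2 fold changes of −1.20 (SE 1.42) and −0.58 (SE 1.12), and Trpm7, a magnesium channel, −0.17 (SE 0.41).

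In single genes of ALN gel against Gel, edgeR called 0 of 15460 genes, with a lowest adjusted p of 0.155. At an unadjusted p under 0.05 there were 1268 genes, 894 higher and 374 lower, against 773 by chance. DESeq2 called 133 genes, 102 higher and 31 lower, and limma-voom with quality weights called 263, with 248 higher and 15 lower. The weights of that fit were lowest for library 1 in each group. They were 0.444 for Gel, 0.511 for ALN gel and 0.275 for Mg-ALN gel library 1, against up to 2.29 for ALN gel library 2. Leaving out ALN gel library 3 gave 1 call by edgeR. The groups did not overlap in 16.1% of genes, against 10% by chance. Of the genes with the smallest p, chosen after the values were seen, Ccl9, a chemokine of myeloid cells and osteoclasts, had 34.6 ± 2.23 CPM in Gel and 349 ± 188 in ALN gel (n = 3, log2 fold change 3.33, SE 0.41). Msantd3 was also higher (1.24, SE 0.20). In the other direction, Selenow, a small selenoprotein, had 43.8 ± 3.21 CPM in Gel and 3.60 ± 3.28 in ALN gel (−3.59, SE 0.64), Creb3l1, a transcription factor that drives collagen secretion in osteoblasts, 219 ± 31.9 and 76.0 ± 30.9 CPM (−1.53, SE 0.30), Aldh1l2, an enzyme of mitochondrial folate metabolism, −1.20 (SE 0.25), and Oas1k, an interferon-induced gene, −1.26 (SE 0.26).

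**Figure D2:**
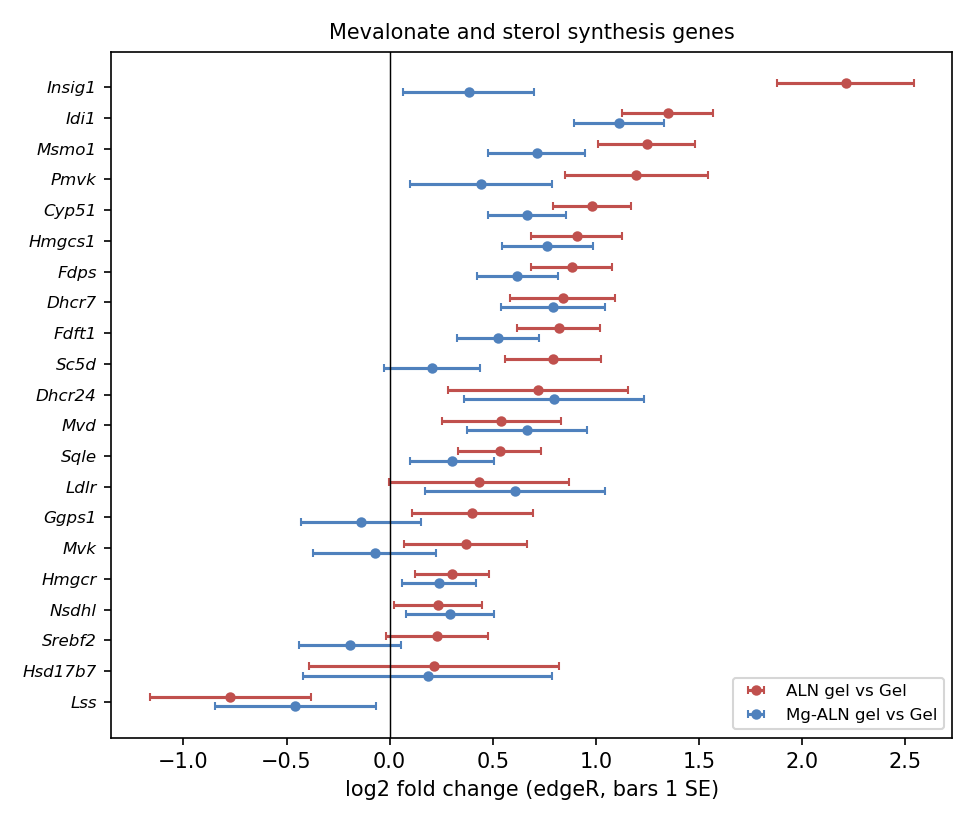
Log2 fold changes with 1 SE (bars) of the 21 tested mevalonate and sterol synthesis genes in ALN gel against Gel (red) and Mg-ALN gel against Gel (blue), from edgeR. The values were positive for 20 members in ALN gel and for 17 in Mg-ALN gel, and Insig1 had 2.21 and 0.38.

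The next comparison, Mg-ALN gel against ALN gel, asks what the magnesium material changed relative to the bisphosphonate gel. Osteoclast genes were lower in Mg-ALN gel for 15 of 15 members, with a median of −1.48 (camera adjusted p = 1.17e-09, and adjusted p = 0.78 with an estimated correlation). There were 4 of 15 that fell when adjusted over the list alone, against 0 over all genes tested. These were Calcr (20.5 ± 3.2 to 1.55 ± 1.29 CPM, n = 3, log2 fold change −3.72, SE 0.78), Tcirg1 (584 ± 83.1 to 272 ± 55.5 CPM), Tnfrsf11a (84.5 ± 12.3 to 34.1 ± 11.3 CPM) and Clcn7, a chloride transporter of the resorbing membrane (132 ± 22.4 to 47.9 ± 25.2 CPM). Acp5 had 6901 ± 2531 CPM in ALN gel and 1447 ± 534 in Mg-ALN gel (−2.25, SE 0.91), and Ctsk had −1.16 (SE 0.75), neither of which passed. The count of 4 was 11 without Gel library 1 or 3, 0 without Mg-ALN gel library 1, and 1 without Gel library 2, any 1 of the ALN gel libraries or Mg-ALN gel library 2, each left out on its own. It was 11 with the mitochondrial share and 13 with the muscle score as a covariate.

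**Figure D3:**
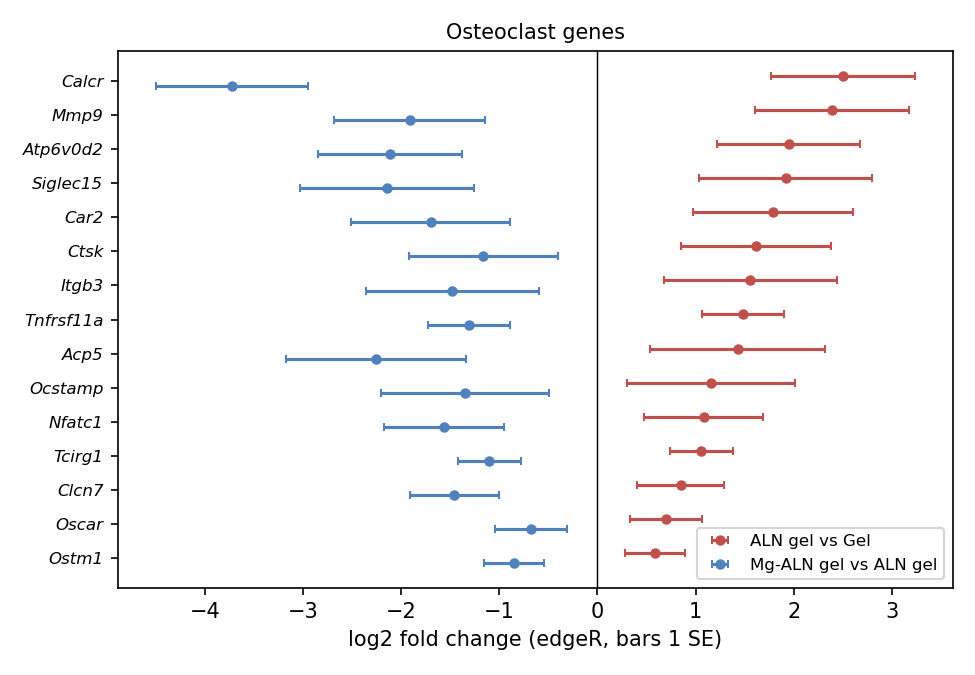
Log2 fold changes with 1 SE (bars) of the 15 tested osteoclast genes in ALN gel against Gel (red) and Mg-ALN gel against ALN gel (blue), from edgeR. Every member was positive in the first and negative in the second, with medians of 1.48 and −1.48.

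By the medians of their lists, matrix genes were higher in Mg-ALN gel than in ALN gel. The list scores of the groups overlapped, with fibrosis scores of −2.26, −0.51 and 0.65 in ALN gel and 0.59, 0.32 and 0.19 in Mg-ALN gel. The fibrosis matrix list had 24 of 25 members with positive values and a median of 0.57 (camera adjusted p = 7.66e-07, and adjusted p = 0.78 with an estimated correlation), and the myofibroblast list 12 of 15 and a median of 0.68 (adjusted p = 0.001, and 0.78 with an estimated correlation). Adjusted over the list alone, 0 members of either passed. Col1a1 had 20358 ± 9235 CPM in ALN gel and 30249 ± 3447 in Mg-ALN gel (n = 3, log2 fold change 0.57, SE 0.64), Col3a1 0.90 (SE 0.89), Postn 1.09 (SE 0.59) and Acta2 1.72 (SE 0.88), none past the threshold. The libraries of the 2 groups with the highest mitochondrial shares were ALN gel library 1 and Mg-ALN gel library 3. The pair left out was another, ALN gel library 1 and Mg-ALN gel library 1, the latter with a share of 11.2%. Without ALN gel library 1 and Mg-ALN gel library 1 the fibrosis median was 0.27 and the call ended (adjusted p = 0.166), as did that of the myofibroblast list (median 0.30, adjusted p = 0.303). The fibrosis median was 0.26 without ALN gel library 1 alone and 1.40 without ALN gel library 3. With the mitochondrial share as a covariate it was 1.01, and the list stayed called at the preset correlation (adjusted p = 1.14e-08). In that fit 1 member passed when adjusted over the list alone. TGF-β response genes had a median of −0.04 while their mean was 0.23 and camera's direction was higher, and the list was not called (adjusted p = 0.281), except at the preset correlation without ALN gel library 3 (median 0.36, 0.0294), with an adjusted p = 0.804 with an estimated correlation over all libraries. Its median lay between −0.22 and 0.36 with 1 library left out, lowest without ALN gel library 1. The ligands, receptors and activators had a median of −0.10 (adjusted p = 0.968), Tgfb1 had 0.26 (SE 0.24) and Ccn2 0.09 (SE 0.79). The direction for Ccn2 turned with Mg-ALN gel library 1 and ALN gel library 1 left out (−1.60).

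By the medians of their lists, stimulus and vessel genes were higher in Mg-ALN gel. Because immediate early genes were also listed as a marker of RNA quality, handling of the samples was not told apart from a stimulus. Immediate early genes had positive values in 13 of 13 members with a median of 1.03 (camera adjusted p = 8.42e-08, and adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone, 2 of 13 rose, against 0 over all genes tested: Ier2, a locus with the biotype pseudogene in the deposited table (65.7 ± 2.80 to 141 ± 0.920 CPM, n = 3), and Btg2, an antiproliferative gene (64.5 ± 6.63 to 107 ± 14.6 CPM). Inflammatory cytokines and chemokines were higher in 13 of 13 with a median of 2.49 (adjusted p = 1.29e-05, and 0.78 with an estimated correlation), with 0 members called over the list alone and a median of 4.26 without ALN gel library 2 and 1.55 without Mg-ALN gel library 1. The endothelial list had 13 of 14 positive and a median of 0.70 (adjusted p = 2.95e-07, and 0.78 with an estimated correlation), or 1.16 without ALN gel library 3, while the list scores of the 2 groups overlapped. The endothelial member Egfl7, a factor secreted by endothelium, rose when adjusted over the list alone, from 55.7 ± 13.3 to 114 ± 7.81 CPM. Timp1, an inhibitor of matrix proteases, rose in the same sense within the protease list, from 247 ± 55.8 to 922 ± 213 CPM (1.90, SE 0.42). Oxidative phosphorylation genes had negative values in 19 of 19 members with a median of −0.50 (adjusted p = 1.15e-06, and 0.78 with an estimated correlation), beside mean mitochondrial shares of 20.9% in ALN gel and 17.8% in Mg-ALN gel.

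Further lists called in Mg-ALN gel against ALN gel lost the call when at least 1 library was left out. They were osteoblast genes (median −0.80, adjusted p = 0.00231), hypoxia and glycolysis (0.49, 0.00296), matrix proteases (0.45, 0.00991), mevalonate and sterol synthesis (−0.23, 0.0104), smooth muscle and pericyte genes (0.61, 0.0144), mature skeletal muscle (−3.27, 0.0144), cell cycle (0.25, 0.0163) and B and plasma cells (−1.72, 0.0173), with 0.78 to 0.829 with an estimated correlation. Without ALN gel library 1 the calls ended for hypoxia and glycolysis (adjusted p = 0.0886), proteases (median 0.18, 0.164), smooth muscle and pericyte genes (0.34, 0.334), mature muscle (−2.13, 0.111) and B and plasma cells (−0.31, 0.191), with 0.56 for cell cycle genes. They ended for the sterol list (−0.10, 0.234) and cell cycle (0.15, 0.0741) without ALN gel library 2, with 0.77 for proteases, and without ALN gel library 3 for cell cycle (0.12, 0.219), with 0.78 for hypoxia and 1.14 for smooth muscle genes. Cell cycle had 0.48 without Mg-ALN gel library 1. Without Mg-ALN gel library 2 the osteoblast (−0.49, 0.268), smooth muscle (0.22, 0.198), cell cycle (0.11, 0.235) and B cell (0.578) calls ended, with 0.69 for proteases, and without Mg-ALN gel library 3 the protease (0.0636), muscle (0.226) and cell cycle (0.14, 0.147) calls. In the sterol list, Insig1 fell when adjusted over the list alone, from 449 ± 127 to 126 ± 42.4 CPM (n = 3, log2 fold change −1.83, SE 0.33), and Fdps had −0.26 (SE 0.20). Mature muscle scores were 3.33, −1.76 and 2.45 in ALN gel and −0.11, −0.48 and −5.90 in Mg-ALN gel. Bglap had 0.08 (SE 1.40), Dmp1 0.19 (SE 1.12) and Trpm7 −0.85 (SE 0.41), none of which passed. The direction for Bglap turned in the limma fits of FPKM (−1.72 with a pseudocount of 1), and that for Dmp1 likewise (−0.33).

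Gene by gene, edgeR called 0 of 15460 genes between Mg-ALN gel and ALN gel, with a lowest adjusted p of 0.217. At an unadjusted p under 0.05 there were 1421 genes, 581 higher and 840 lower, against 773 by chance. DESeq2 called 184 genes, 58 higher and 126 lower, and limma-voom with quality weights called 2. With the mitochondrial share as a covariate edgeR called 1. The groups did not overlap in 16.5% of genes, against 10% by chance. Among the genes with the smallest p, chosen after the values were seen, Oas1k went from 5.93 ± 1.53 to 25.8 ± 1.90 CPM (n = 3, log2 fold change 2.12, SE 0.27) and Selenow from 3.60 ± 3.28 to 76.2 ± 35.6 CPM (4.39, SE 0.66). The lower ones were Ccdc3 (28.3 ± 3.99 to 5.00 ± 1.34 CPM, −2.49, SE 0.37), Sema5a, a guidance cue (118 ± 27.4 to 24.1 ± 9.50 CPM), Gsap (137 ± 14.3 to 51.7 ± 5.28 CPM) and Cd4, the co-receptor of helper T cells, which rat macrophages also carry (175 ± 43.9 to 60.7 ± 11.2 CPM). Cd4 also passed when adjusted over the list of T and NK cells alone, and Lipe, the hormone-sensitive lipase, over the adipocyte list alone (1.04, SE 0.28).

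The last pairwise comparison, Mg-ALN gel against Gel, asks how the combined material differed from the carrier. Mevalonate and sterol synthesis genes were higher in Mg-ALN gel for 17 of 21 members, with a median of 0.44 (camera adjusted p = 2.36e-05, and adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone, 6 of 21 rose, against 0 over all genes tested. Among them were Idi1 (11.8 ± 1.06 to 25.6 ± 4.40 CPM, n = 3, log2 fold change 1.11, SE 0.22), Fdps (43.9 ± 0.813 to 67.5 ± 14.2 CPM, 0.62, SE 0.20), Hmgcs1, which makes the precursor of mevalonate (0.77, SE 0.22), Cyp51 (0.67, SE 0.19), Msmo1 (0.71, SE 0.23) and Dhcr7, the last enzyme of cholesterol synthesis (0.79, SE 0.25). That count of 6 was between 0 and 2 without any 1 of the 9 libraries, and 1 with RLE scaling. It was 0 without Gel library 1, Gel library 2, Gel library 3 or Mg-ALN gel library 2. Oxidative phosphorylation genes had a median of 0.30 with 16 of 19 positive (adjusted p = 0.00245, and 0.78 with an estimated correlation), or 0.17 without Gel library 3. The mean mitochondrial share was 9.01 ± 7.35% in Gel and 17.8 ± 12.0% in Mg-ALN gel, and with that share as a covariate the call ended (adjusted p = 0.28).

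The fibrosis matrix list did not separate Mg-ALN gel from Gel, with a median of −0.04, 11 members positive and 14 negative (camera adjusted p = 0.995). With the mitochondrial share as a covariate its median was 0.82 and it was called at the preset correlation (adjusted p = 4.68e-04), while without that covariate the adjusted p = 0.999 with an estimated correlation, which was not run with it. TGF-β response genes were not called (median 0.02, mean −0.05 with camera's direction lower, adjusted p = 0.821), and the ligands, receptors and activators had a median of −0.41 (adjusted p = 0.0166, and 0.78 with an estimated correlation), a call that was lost without Mg-ALN gel library 3 (adjusted p = 0.0664), with a median of −0.25 without Mg-ALN gel library 1. Col1a1 had −1.01 (SE 0.64) with no overlap between the groups, Col3a1 0.38 (SE 0.88), Postn 0.23 (SE 0.58), Tgfb1 −0.24 (SE 0.24), Ccn2 0.14 (SE 0.79), Acta2 0.48 (SE 0.86), Ctsk 0.45 (SE 0.75), Acp5 −0.83 (SE 0.88), Bglap −1.12 (SE 1.42), Dmp1 −0.39 (SE 1.12) and Trpm7 −1.02 (SE 0.41). None passed, and the direction turned without Gel library 1 for Acp5 (1.15) and Bglap (0.99).

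**Figure D4:**
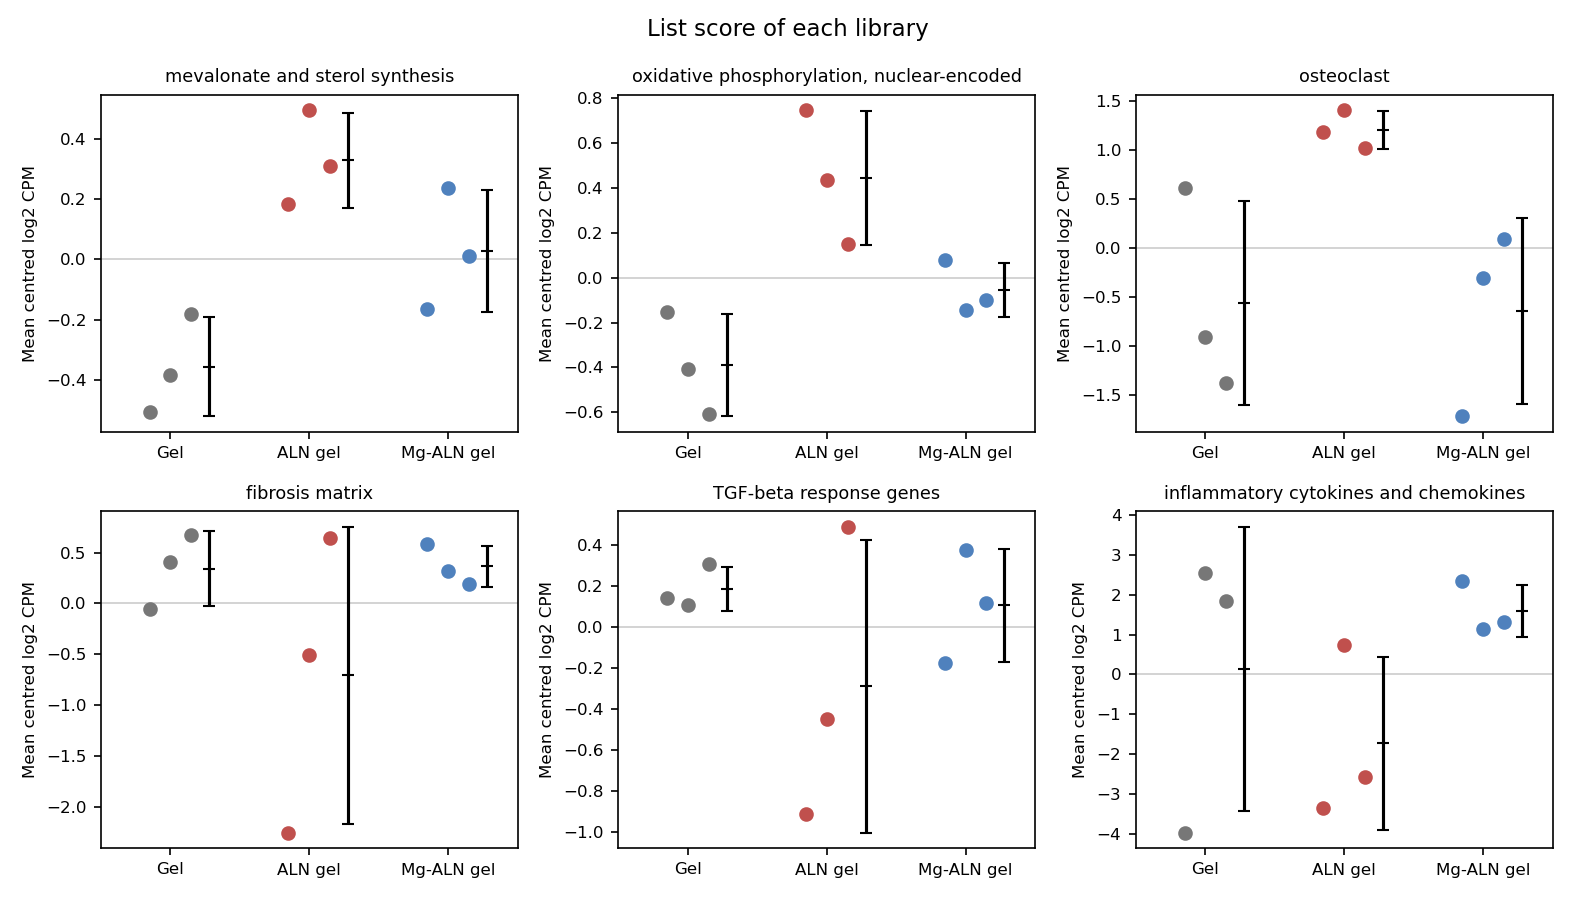
List score (mean centred log2 CPM of the members) of each library (points) for 6 lists, with the mean and SD of each group (bars, n = 3). The osteoclast scores of ALN gel, 1.18, 1.40 and 1.02, lay above those of the other 6 libraries, and the fibrosis matrix scores of ALN gel spread from −2.26 to 0.65.

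Other lists called in Mg-ALN gel against Gel lost the call when at least 1 library was left out. They were endothelium (median 0.53, adjusted p = 7.81e-04), mitochondrially encoded transcripts (1.19, 0.0024), cell cycle (0.34, 0.00245), osteoblast (−1.29, 6.66e-04), chondrocyte (−1.61, 0.0135), mature skeletal muscle (−4.40, 0.0199), B and plasma cells (−1.29, 0.0209) and magnesium transport (−0.20, 0.0413), with 0.78 to 0.837 with an estimated correlation. Without Gel library 1 the osteoblast call ended (median −0.19, adjusted p = 0.164), as did that of B and plasma cells, whose median turned positive (0.34, 0.304), with 2.17 for mitochondrially encoded transcripts and 0.68 for cell cycle. Without Gel library 2 the cell cycle (0.19, 0.190) and magnesium transport (−0.07, 0.124) calls ended, and without Gel library 3 those of mature muscle, whose median turned positive (0.45, 0.520), chondrocyte genes (−1.06, 0.124) and magnesium transport (0.0820), with 0.18 for cell cycle. The magnesium transport call also ended without ALN gel library 1 (0.0515) or Mg-ALN gel library 1 (0.0951), and without the latter cell cycle had 0.56 and B and plasma cells −2.05. Without Mg-ALN gel library 2 the endothelial (0.23, 0.0530), osteoblast (0.180), chondrocyte (0.121), cell cycle (0.20, 0.0968), B cell (−0.85, 0.772) and muscle (0.0880) calls ended, with −0.47 for magnesium transport. Without Mg-ALN gel library 3 those of mitochondrially encoded transcripts (0.26, 0.226), muscle (0.396), cell cycle (0.0516) and magnesium transport (0.0734) ended, with −2.63 for chondrocyte genes and −2.01 for B and plasma cells. The inflammatory list was called in the higher direction (adjusted p = 0.0209) although its median was −0.07, with a mean of 0.14 (adjusted p = 0.829 with an estimated correlation). That call ended without Gel library 1 (median −0.67, adjusted p = 0.174), without Mg-ALN gel library 1 (−0.65, 0.145) and with the replicate number as a block (0.264), and the median was positive without Gel library 2 (1.06), Gel library 3 (0.25), Mg-ALN gel library 2 (0.29) or Mg-ALN gel library 3 (0.27), and −0.12 without ALN gel library 2 or 3. S100a4, a calcium-binding protein of motile mesenchymal and myeloid cells, rose when adjusted over the myofibroblast list alone, from 255 ± 75.0 to 880 ± 578 CPM (n = 3), and Egfl7 over the endothelial list alone, from 48.2 ± 0.764 to 114 ± 7.81 CPM. By single genes, edgeR called 0 of 15460 (lowest adjusted p = 0.530), with 1439 at an unadjusted p under 0.05, 839 higher and 600 lower, against 773 by chance. DESeq2 called 51 genes, 24 higher and 27 lower, and limma-voom with quality weights 0. The groups did not overlap in 18.3% of genes, against 10% by chance. Of those with the smallest p, chosen after the values were seen, Nxt1, a factor of mRNA export (1.28, SE 0.24), and Fam167b (1.38, SE 0.26) were higher, and Flrt2, a cell adhesion protein (23.0 ± 0.537 to 7.51 ± 1.02 CPM, −1.62, SE 0.29), Abca9 (−2.49, SE 0.49) and Arhgap39 (−1.03, SE 0.21) were lower. Pcdh10, a protocadherin, had 2.01 ± 2.03 CPM in Gel and no counts in Mg-ALN gel.

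Among the 3 groups together, edgeR called 0 genes (lowest adjusted p = 0.277) and 1437 reached an unadjusted p under 0.05. DESeq2 called 247, limma-voom with quality weights 12, and edgeR without ALN gel library 3 called 1. No gene passed by edgeR both in ALN gel against Gel and, in the opposite direction, in Mg-ALN gel against ALN gel. DESeq2 gave 41 such genes and limma-voom with quality weights 2. At an unadjusted p under 0.05, 312 genes were higher in ALN gel than in Gel and lower in Mg-ALN gel than in ALN gel, and 136 the other way. Because both comparisons use the ALN gel libraries, simulated data with no effect gave 57.1 and 112, and independent lists of these sizes 48.6 and 14.1. The fold changes of the 2 comparisons correlated across genes with r = −0.473 against −0.497 in the simulations, with a covariance of −0.337 against −0.271. For ALN gel and Mg-ALN gel, both against Gel, 268 genes were higher in both and 63 lower in both, against 110 and 58.5 in the simulations and 48.5 and 14.5 for independent lists. Their correlation was 0.354 against 0.50 simulated, and the covariance 0.237 against 0.273. The simulated data share the same libraries, but hold no structure common to many genes or to a replicate number. An excess over them may therefore come from such structure in the shared libraries and does not by itself show a reversal or a shared effect. A group of 3 libraries cannot be split into parts of at least 2 libraries each, so this could not be tested. In exact permutation tests of the list scores over the 3 groups, oxidative phosphorylation had the smallest possible p (0.00357, adjusted over 34 lists 0.121), and mevalonate and sterol synthesis had 0.0107 (adjusted 0.182). Of the 34 lists, the scores of 3, 5 and 4 did not overlap between groups in the 3 comparisons, against 3.4 by chance. With an estimated correlation camera called 0 lists (lowest adjusted p = 0.78), and fry called 0 (lowest 0.126). The adjustment gave many lists that same 0.78, so it does not rank them. In ALN gel against Gel, unadjusted camera p with that correlation was 0.0144 for mevalonate and sterol synthesis and 0.0166 for oxidative phosphorylation. It was 0.0619 for osteoclast genes, 0.149 for the fibrosis matrix list and 0.222 for TGF-β response genes. The unadjusted fry p was 0.00124, 0.00265, 0.0297, 0.165 and 0.279 in this order. The 12 lists called in no comparison, with their lowest adjusted p by camera, were adipocyte (0.948), interferon response (0.342), macrophage (0.791), megakaryocyte and mast cell (0.273), muscle precursor and regeneration (0.0796), neutrophil and granulocyte precursor (0.0563), osteocyte (0.0756), Schwann cell and nerve (0.541), T and NK cell (0.791), tendon and ligament (0.813), TGF-β response (0.0796) and Wnt antagonists (0.813).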

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

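The alternatives that left out mitochondrial genes, used the mitochondrial share as a covariate, or left out ALN gel library 1 with Mg-ALN gel library 1 were chosen after the results were seen. Of the counts of genes, 160 stayed within 1.5 times the value reported and 20 moved. Of the values for lists, 526 kept their direction and side of the threshold, 171 lost the call, 4 gained it and 20 turned direction. Apart from the fibrosis matrix and TGF-β response lists, only lists called in the main fit were followed. Lists not followed could not gain a call, so losses and gains cannot be weighed against each other. The other called lists were not followed under the alternative scalings, filters, limma fits or fits of 2 groups. Of the values for single genes 1842 were kept, 61 gained a call and 54 turned. Except where stated, the cause of these changes was not tested. Counts of list members adjusted over the list alone moved in 62 cases and stayed in 48. At the depth and spread of these libraries, simulated 2-fold changes were not recovered, and Sost rests on 2 to 119 counts per library.

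By DESeq2 the called genes were 133 in ALN gel against Gel, 184 in Mg-ALN gel against ALN gel, 51 in Mg-ALN gel against Gel, 247 among the 3 groups and 41 moved back. By limma-voom with quality weights, which were lowest for library 1 in each group, they were 263 in the first of these and 2 in the next. That fit called 12 among the 3 groups and 2 moved back. The log2 fold change of Sost was −4.17 by DESeq2 in Mg-ALN gel against ALN gel and 3.83 by limma-voom in ALN gel against Gel. Over all alternatives the adjusted p of Sost ranged from 0.0397 to 1 in ALN gel against Gel, from 0.00195 to 0.752 in Mg-ALN gel against ALN gel and from 0.504 to 0.938 in Mg-ALN gel against Gel.

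The fibrosis matrix median in Mg-ALN gel against Gel was −0.046 with RLE and −0.033 with upper-quartile scaling, −0.106 with no low-count filter, 0.028 on log2(FPKM + 0.1), −0.069 with only the 2 groups compared, −0.073 without mitochondrial genes and 0.82 with the mitochondrial share as a covariate, with camera's direction turned in each (adjusted p from 4.68e-04 to 0.999 over all alternatives). With an estimated correlation and with fry its medians of −0.55 in ALN gel against Gel and 0.57 in Mg-ALN gel against ALN gel were no longer called (adjusted p from 3.68e-13 to 0.78 and from 3.04e-14 to 0.78 over all alternatives).

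Ccn2 in ALN gel against Gel had −0.037 with no low-count filter, −0.54 by limma-voom, −0.25 and −0.26 in the 2 FPKM fits (pseudocounts 1 and 0.1) and −0.035 without mitochondrial genes. By limma-voom with quality weights, Bglap had 0.47 in ALN gel against Gel and −3.01 in Mg-ALN gel against ALN gel, Ccn2 −0.54 in the latter and −1.08 in Mg-ALN gel against Gel, Dmp1 −0.62 in Mg-ALN gel against ALN gel, and Acp5 and Acta2 0.99 and −0.35 in Mg-ALN gel against Gel. On log2(FPKM + 1) and log2(FPKM + 0.1), Mg-ALN gel against ALN gel gave −1.72 and −1.78 for Bglap, −0.14 and −0.14 for Ccn2 and −0.33 and −0.49 for Dmp1, and Mg-ALN gel against Gel gave 0.038 and 0.039 for Acp5 and −0.39 and −0.40 for Ccn2. With the mitochondrial share as a covariate, Col3a1 had 0.12, the fibrosis matrix list −0.13 and the erythroid list −0.34 in ALN gel against Gel, the TGF-β response list 0.075 and the mitochondrially encoded list −0.048 in Mg-ALN gel against Gel, and edgeR called 1 gene in Mg-ALN gel against ALN gel. Without ALN gel library 1 and Mg-ALN gel library 1, Mg-ALN gel against ALN gel gave −0.66 for Bglap, −1.60 for Ccn2 and 0.27 for the fibrosis matrix list, and Mg-ALN gel against Gel gave −1.32 for Ccn2 and −0.27 for Acta2.

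By the correlations of their deviations, libraries of Gel and ALN gel with the same number were the closest, which was not so for Mg-ALN gel with either. Only 4 of 9 libraries correlated best with their own number, so a pairing is not established. With the replicate block, which treats all 3 groups as sharing the numbers, edgeR again called 0 genes in each comparison, and 14, 15 and 11 of the called lists stayed called. The block gave −0.40 for the TGF-β response list in ALN gel against Gel, now called (adjusted p = 0.0468, range over alternatives 0.0103 to 0.78), 0 osteoclast genes called over the list alone and −0.094 for Ccn2 there, with no called list lost in that comparison, −0.77 for Bglap in Mg-ALN gel against ALN gel, and, in Mg-ALN gel against Gel, 0.00018 for Acp5, −0.048 for Ccn2 and 0.17 for the fibrosis matrix list.

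With each library left out in turn, values in ALN gel against Gel ranged from −1.70 to 0.91 for Bglap, −0.96 to 0.33 for Ccn2, −1.82 to 0.10 for Dmp1, −1.84 to 0.018 for Col3a1 and −0.77 to −0.15 for the TGF-β response list, with 0 to 1 genes called there and 0 to 1 among the 3 groups. In Mg-ALN gel against ALN gel they ranged from −1.34 to 1.07 for Ccn2, −0.55 to 1.43 for Dmp1, −0.98 to 0.71 for Bglap and −0.22 to 0.36 for the TGF-β response list. In Mg-ALN gel against Gel they ranged from −2.16 to 0.32 for Sost, −1.33 to 1.15 for Acp5, −2.18 to 0.99 for Bglap, −1.13 to 0.29 for Dmp1, −1.30 to 0.56 for Ccn2, −0.23 to 0.82 for Acta2, −0.23 to 0.085 for the TGF-β response list, −0.67 to 1.06 for the inflammatory list and −0.16 to 0.14 for the fibrosis matrix list.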

Other observations

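The genes named here outside the fixed lists, the tests with the mitochondrial share, of the other osteocyte genes, without ALN gel library 1 and of splits within replicate numbers were chosen only after the result was seen. Some cartilage and inflammatory genes had their lowest or highest mean in Mg-ALN gel. Col2a1, the collagen of cartilage, had 117 ± 164 CPM in Gel, 43.4 ± 21.2 in ALN gel and 0.732 ± 0.376 in Mg-ALN gel (n = 3 each), and DESeq2 called it lower in Mg-ALN gel than in ALN gel (adjusted p = 0.0333) and than in Gel (adjusted p = 0.00564), while edgeR did not. Its Gel libraries had 46.8, 0.113 and 305 CPM, so that Gel library 2 lay below each Mg-ALN gel library. Il6 had 13.4 ± 10.9, 2.0 ± 2.76 and 45.4 ± 17.4 CPM and the neutrophil chemokine Cxcl1 52.1 ± 47.3, 6.76 ± 5.46 and 72.1 ± 4.90 CPM, both called by DESeq2 in Mg-ALN gel against ALN gel (adjusted p = 0.0218 and 0.0141). Against Gel, edgeR gave log2 fold changes of 1.76 (SE 1.16) for Il6 and 0.47 (SE 0.88) for Cxcl1, neither of which passed. Gel library 2, with 99.9 CPM of Cxcl1, lay above each Mg-ALN gel library. Of the 13 genes of the inflammatory list, 6 were higher and 7 lower in Mg-ALN gel than in Gel.

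Other genes had their lowest mean in ALN gel. Serpina3n, an acute-phase protease inhibitor, had 277 ± 181 CPM in Gel, 31.2 ± 17.9 in ALN gel and 225 ± 88.3 in Mg-ALN gel (n = 3 each), with log2 fold changes of −3.15 (SE 0.68) and 2.85 (SE 0.67) in ALN gel against Gel and Mg-ALN gel against ALN gel. Ptx3, a soluble pattern receptor, had 140 ± 147, 12.8 ± 7.65 and 78.7 ± 34.9 CPM. Mmp9, a gelatinase held by the osteoclast list, was the reverse, with 1219 ± 1226, 6391 ± 1406 and 1699 ± 939 CPM.

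Mevalonate and sterol synthesis genes were higher in both bisphosphonate groups than in Gel by the medians of the list. With the osteoclast score as a covariate the list stayed called in ALN gel against Gel (camera adjusted p = 2.67e-07, median 0.69) and in Mg-ALN gel against Gel (6.41e-05, median 0.49). With the mitochondrial share it also stayed called (4.2e-14 and 1.36e-05, medians 0.78 and 0.49). The medians without a covariate were 0.72 and 0.44, so neither covariate shrank them by much. These calls are at the preset correlation (adjusted p = 0.78 with an estimated correlation and no covariate, and not run with one). At it, splits other than by group gave camera p-values down to 3.95e-08 and 4.13e-06 in these comparisons, so kept calls cannot exclude either cause. A sterol response that reaches beyond the pathway stays open. Of 10 further SREBP2 targets 9 were tested, and their mean differed by 0.0495 between the 6 libraries and Gel (exact p = 0.798), while 5 LXR targets differed by −0.247 (exact p = 0.381). A response to the drug's enzyme block is a hypothesis that these data neither establish nor exclude.

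Sost was higher in each ALN gel library than in each Gel library. The other 8 tested osteocyte genes did not rise with it as a set, with a median log2 fold change of −0.99 (SD 1.32, range −3.87 to 0.47). For those genes this argues against a gain in osteocytes of all kinds as large as the change of Sost, but not against a smaller one. Fgf23, the lowest of them, had 6.88 CPM in Gel library 2 against 0.356 and 0.752 in Gel libraries 1 and 3. Dmp1 turned to 0.10 without Gel library 1, and the median of these genes was not taken with libraries left out. The osteocyte list was not called in this comparison (camera adjusted p = 0.0756). With the mitochondrial share as a covariate the log2 fold change of Sost was 2.64 (SE 0.70, edgeR unadjusted p = 0.00551), so most of the difference remained. Regulation within osteocytes or a different mix of osteocyte stages was not tested.

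By the medians of their lists, oxidative phosphorylation genes were higher and fibrosis matrix genes lower in ALN gel than in Gel, and ALN gel library 1 had both the highest mitochondrial share and the lowest fibrosis score. At the preset correlation, oxidative phosphorylation stayed called with the mitochondrial share (adjusted p = 1.21e-12) or the muscle score (2.49e-15) as a covariate and without that library (1.68e-14). With an estimated correlation and no covariate the adjusted p was 0.78, and it was not run with one. At the preset correlation a split other than by group gave a camera p of 1.74e-08, so kept calls cannot exclude these causes for this list. Its members called over the list alone went from 15 to 0 both with the mitochondrial share and without that library, as the median went from 0.88 (SD over members 0.227) to 0.68 (SD 0.162) and 0.66 (SD 0.146) and a degree of freedom was lost. For the fibrosis matrix list (adjusted p = 0.78 with an estimated correlation), leaving out the library left a call at the preset one (adjusted p = 0.00922, median −0.30), and the mitochondrial share as a covariate ended it (adjusted p = 0.0648), as the median went from −0.55 (SD over members 0.462) to −0.13 (SD 0.644), so the effect shrank and its spread grew. Whether that share marks RNA quality, cell content or a biological change in the tissue was not tested.

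In 3 libraries against 3, only 10 splits exist, too few for a share under 0.05. For ALN gel against Gel, 10 of 10 splits called as many genes by edgeR as the real 0 (highest other 153), 3 reached its 1268 at unadjusted p (1701), 3 its 133 by DESeq2 (715), 2 its 263 by limma-voom (736) and 8 its 14 lists (21). The split with 153 calls set Gel library 1 with ALN gel libraries 1 and 3, the libraries with the lowest inflammatory scores (−3.97, −3.36 and −2.58), against the rest, which points to structure among the libraries other than the groups. Splits gave a camera p as small as the real one for the fibrosis matrix list in 4 of 10 (real 1.2e-08, lowest other 4.23e-12), for TGF-β response in 4 (0.0367, 0.00123), and for mevalonate synthesis (4.61e-13, 3.95e-08), oxidative phosphorylation (1.04e-17, 1.74e-08) and osteoclast genes (2.24e-12, 2.62e-11) in 1, the real split. Libraries of the same number were the closest between these 2 groups, though a pairing is not established. The 3 other splits that part all 3 same-number pairs gave 259, 84 and 336 genes at unadjusted p. They gave 5, 1 and 0 genes by DESeq2, 0 by limma-voom, and 21, 10 and 14 lists. Each split with more genes than the real one at unadjusted p held Gel library 1 and ALN gel library 1 together. With 4 splits that part the pairs, the real one included, no share under 0.05 can be had. For Mg-ALN gel against ALN gel the counts were 10 of 10 by edgeR (real 0, highest other 0), 2 at unadjusted p (1421, 1551), 2 by DESeq2 (184, 248), 1 by limma-voom (2, 0), 3 for lists (15, 19), 3 for fibrosis matrix (6.01e-08, 2.2e-17), 7 for TGF-β response (0.16, 0.00956), 3 for mevalonate synthesis (0.00276, 6.13e-04), 1 for oxidative phosphorylation (1.01e-07, 1.59e-07) and 1 for osteoclast genes (4.59e-11, 1.15e-06).

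For Mg-ALN gel against Gel the counts of splits were 10 by edgeR (real 0, highest other 1), 1 at unadjusted p (1439, 1032), 3 by DESeq2 (51, 128), 10 by limma-voom (0, 1), 6 for lists (12, 16), 10 for fibrosis matrix (0.995, lowest other 0.0111), 7 for TGF-β response (0.684, 0.172), 1 for mevalonate synthesis (2.77e-06, 4.13e-06), 3 for oxidative phosphorylation (4.63e-04, 4.97e-05) and 10 for osteoclast genes (0.828, 8.38e-17). Over 100 of the 280 splits into 3 groups, the real one included, 8 reached its 1437 genes at unadjusted p (highest other 1815), so chance is not excluded for these. The real counts by edgeR of adjusted calls and of moved-back genes were 0, which any split reaches, so the 100 of 100 found for each (highest other 82 and 44) decide nothing.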
